A study of Macaca fascicularis with 34 samples.

How the data were processed

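Transcripts of 34 single cells of cynomolgus monkeys (Macaca fascicularis) were measured by sequencing of amplified complementary DNA. Per the labels, 25 cells came from embryos at embryonic day (E) 13, 14, 16, 17 and 20, and 9 came from male gonads at E36, E47 and E55. The extract protocol in the labels names cDNA synthesis and amplification from single cells followed by SOLiD library construction, and the series description calls the method SC3-seq, which reads the 3' ends of transcripts. The submitters' processing notes list cutadapt 1.3, TopHat 1.4.1 and Cufflinks 2.2.0 without saying what each was used for. The genome build and the annotation are not given in the sources used here. The labels name no cell type and no animal.

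The authors deposited 1 expression table whose name gives RPM, reads scaled to a common library total. The deposited values are on a log2 scale, log2(RPM + 1): back-transformed as a power of 2 minus 1, each column summed to between 992085 and 995711, and low values lay on whole multiples of 1 step per column. Values were therefore back-transformed to RPM, and the reads of each cell were recovered as the inverse of the step. Between 99.7% and 100% of a cell's low values were whole within a tolerance of 0.1 read. The recovered depth ran from 472185 to 3556558 reads per cell, with a median of 2.00e+06. The table holds 28551 genes, of which 19912 are protein-coding and 8639 noncoding. They lie on 20 autosomes and the X chromosome, and 0 lie on a Y or mitochondrial chromosome. A human gene symbol is paired with 17683 genes in the table, and genes are named here by that symbol, as FAM54A for MTFR2 or CTSL2 for CTSV. Chromosomes are given as the table lists them, with no coordinates. All columns of the table belong to the 34 cells. No pair of cells shared a column: the most similar pair, E16 cell 8 and E20 cell 1, had a Pearson correlation of 0.883 across genes and 0 identical values above 0.

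Each sample is 1 cell and no animal is named, so each stage counted as 1 sample. Cells were not taken as replicates of a stage, and no difference between groups was tested or given a p-value or standard error. The cells of E20 and of E36 were only screened for single cells lying apart, by the gap to the nearest cell over the range against Dixon's 95% critical value. Means are over cells, standard deviations (SD) give the spread between cells, and a difference is the difference of mean log2(RPM + 1). Folds are ratios of mean RPM. Summed reads carry exact Poisson intervals at 95%, and a count of 0 allows up to 3 reads of the summed depth. The reads come from amplified cDNA without molecular identifiers, so these intervals and limits cover counting error only.

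The following choices were made before the data were examined. The comparisons were gonad against embryo (9 and 25 cells), E20 against E16 (8 and 11 cells) and E55 against E36 (2 and 6 cells). The 22 gene lists covered germ cell specification, the pluripotency core, the primed epiblast, late germ cell and piRNA pathway genes, meiosis, the DNA methylation machinery, histone and arginine methylation, the amnion, gastrulation and mesoderm, endoderm, trophoblast, gonadal somatic cells, blood and endothelium, neural and surface ectoderm, the WNT and BMP response, proliferation, migration and adhesion, cell stress, oxidative phosphorylation, X inactivation and Y-linked genes, HOX genes and ribosomal proteins. Some lists shared members and are not independent of each other. For example, T was in the germ cell specification and mesoderm lists, and SOX17 in the germ cell specification and endoderm lists. The amnion list shared HAND1 with mesoderm, MSX1, MSX2 and BMP4 with WNT and BMP, and GATA3, KRT7 and TFAP2A with trophoblast. A member counted as measured at a mean of at least 1 RPM in 1 of the groups compared. A list was summarised by the median difference over its measured members and by the members that differed at least 2-fold. Its percentile is its place among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean expression. This percentile describes the list and is not a p-value. X inactivation and Y-linked genes were read gene by gene, and the sole member of the Y-linked genes in the table, the gene paired with human EIF1AY, is placed on chromosome 20 there.

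Named genes followed a rule. Among genes with a mean of at least 50 RPM in the higher group and at least 15 RPM in 80% of its cells, the 12 with the highest and the 12 with the lowest difference were named, or 6 and 6 for E55 against E36. Genes without a symbol were skipped, and a few genes that the rule names are not reported here. From a list, 2 to 4 members with the highest level or the largest difference served as examples, and any member of the germ cell specification, pluripotency, late germ cell, DNA methylation and amnion lists could be named. Values of single cells named outside this rule were chosen after they were seen. A gene counted as detected in a cell at 15 RPM.

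Cells were clustered by average linkage on 1 minus the Pearson correlation over the 2000 most variable genes with a mean of at least 5 RPM, with the number of clusters from 2 to 6 chosen by the mean silhouette. A cluster was given the name of a cell type when at least 3 of its markers averaged 15 RPM or more and its leading genes did not go against the name. Clusters were not tested against each other.

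The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. The comparison of means was tested on simulated data: with known changes of 1 and 2 log2 units put into 50 genes each of a table of 28551 genes, the median estimates for gonad against embryo were 0.979 and 1.97, and -1.07 and -1.96 for decreases. For E55 against E36 they were 1.08, 1.85, -1.13 and -2.16, and the sign was right for 86% of the genes raised by 1 unit. The changed genes all averaged at least 50 RPM, and the simulated cells of a group shared the same mean levels. The simulation therefore does not cover list members near 1 RPM or groups of mixed cells.

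Alternatives changed 1 choice at a time, except for 1 added setting that joined 2 of them, the germ-cell-like cluster and the leaving out of 3 gonad cells. They were pseudocounts of 0.1 and 10 in place of 1, no minimum level or a minimum of 15 RPM for list members, medians over cells, median-of-ratios size factors over the 3119 genes detected in every cell, the log2 ratio of mean RPM, and each cell left out in turn. Gonad against embryo was also computed from stage means, for E36 against E20, without each embryo stage, and within label code MS11, the sole code carried by gonad cells and also by the E17 cells. E20 against E16 was also computed within label code MS09. Detection used 1 and 50 RPM and thinning of every cell to 472185 reads, and clustering used Ward linkage, 500 genes or all genes. Added after the data were seen were the comparisons within the germ-cell-like cluster, those without the gonad cells rich in somatic transcripts, and E20 against E16 with thinned cells. A list median had a direction at 0.5 log2 units or more. It counted as turned when such a value changed sign, and otherwise as moved when it shifted by at least 1 SD between cells. A value of exactly 0 had no rule of its own. Lists with a direction went to exactly 0 in 3 values for gonad against embryo, 3 for E20 against E16 and 6 for E55 against E36. Some of these counted as within 1 SD. Counts of members counted as moved beyond 1.5 times. Tests for changed genes, gene-set enrichment, pseudotime and allele or splice analyses were left out, because the table holds gene levels of single cells without animals.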

Results

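Gene expression was measured in 34 single cells of cynomolgus monkeys, 25 from embryos around the time when primordial germ cells, the precursors of eggs and sperm, appear, and 9 from male gonads. The embryo cells came from E13 (3 cells), E14 (1 cell), E16 (11 cells), E17 (2 cells) and E20 (8 cells). The gonad cells came from E36 (6 cells), E47 (1 cell) and E55 (2 cells). Depth lay between 472185 and 775712 reads per cell at E13 and was 2310049 reads in the E14 cell. At E16 it ran from 1933053 to 3556558 reads, at E17 from 2678837 to 2799189 and at E20 from 1072305 to 2711020. Gonad cells held 809116 to 2944987 reads at E36, 1102515 at E47, and 975816 and 1380681 at E55. Between 5102 and 8106 genes reached 15 RPM in a cell, with stage medians of 6298 at E13, 6658 at E16, 6875 at E20 and 5562 at E36. No animal is named, so each stage stands as 1 sample, differences are described with the spread between cells (SD, n cells), and no difference was tested. Label codes in the sample titles follow the stages: E13 carried MS10, E14 MS13, E16 and E20 cell 8 MS09, the other E20 cells MS08, and E17 and the gonad cells MS11.

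The 34 cells fell into a larger group with germ cell transcripts and a smaller one with mesodermal transcripts. The 25 germ-cell-like cells averaged at least 15 RPM for 14 of 14 germ cell markers, and 12 of these also had a median of at least 15 RPM. DAZL and DDX4 were among the 14 through the gonad cells alone, since the 16 embryo cells of this group held 0 reads of DAZL and, summed, 0.667 RPM of DDX4. The group's leading genes included TFAP2C, a transcription factor of primordial germ cells, with the RNA-binding protein genes CPEB1 and ELAVL2. This group held every E13, E14 and gonad cell, 10 of the 11 E16 cells, E17 cell 1 and E20 cell 8. The other 9 cells, E16 cell 8, E17 cell 2 and E20 cells 1 to 7, averaged at least 15 RPM for 9 of 10 mesoderm markers. Of these markers 6 also had a median of at least 15 RPM. Leading genes of this group were PDGFRA, a growth factor receptor of mesoderm, HAND1, a mesoderm and amnion transcription factor, and the matrix genes HAPLN1, VCAN, FN1 and COL1A1. These 9 cells were mixed: 7 of 14 germ cell, 3 of 10 amnion, 4 of 8 epiblast and 2 of 8 endoderm markers also had a median of at least 15 RPM. E16 cell 8 held 8 of 8 endoderm markers, and the other 8 cells 0 to 3. The mean silhouette was low, 0.191 for 2 clusters and 0.146 for 3, and the smaller cluster held between 8 and 10 cells with other genes or linkage.

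**Figure D1:**
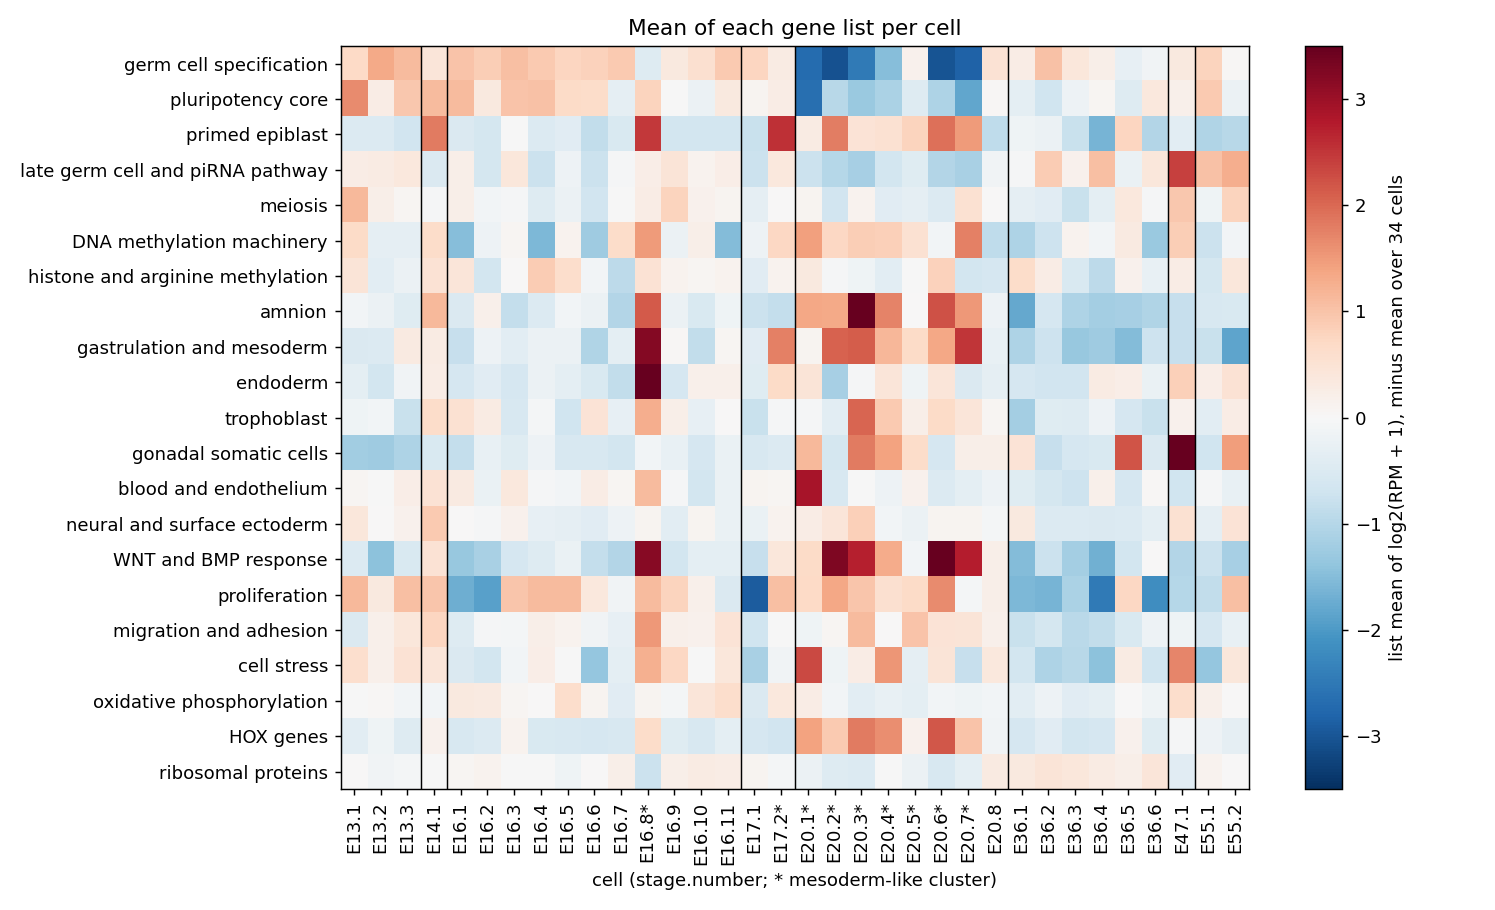
Heat map of 21 gene lists (vertical) in 34 cells ordered by stage (horizontal), where colour gives a list's mean log2(RPM + 1) in the cell minus its mean over the 34 cells and an asterisk marks the 9 mesoderm-like cells. Germ cell specification genes were low in most E20 cells, and gonadal somatic genes were highest in the E47 cell at 6.55.

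Gonad cells were compared with embryo cells to see how the germ line differs between its first days and its time in the male gonad. DAZL and DDX4, RNA-binding genes of gonadal germ cells, were found almost only in gonad cells. DAZL averaged 80.7 ± 99.4 RPM in the 9 gonad cells and 0.0337 RPM in the 25 embryo cells, with 1 read among all embryo libraries. DDX4 averaged 79.1 ± 55.8 RPM in gonad cells and 0.514 ± 1.68 RPM in embryo cells. Summed over cells, DAZL had 66.6 RPM in gonad cells (exact Poisson interval 62.6 to 70.9) and 0.0204 RPM in embryo cells (0.000517 to 0.114). DAZL reached 15 RPM in 6 of 9 gonad cells and DDX4 in 7 of 9, and E36 cells 3 and 5 lacked DDX4. Proliferation and mesoderm genes were lower in gonad cells.

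Of 21 measured late germ cell and piRNA pathway genes, 11 were at least 2-fold higher in gonad cells and 2 were lower, with a median difference of 1.02 (above 100% of matched random lists). GTSF1, a piRNA pathway factor, averaged 98.3 ± 70.1 RPM against 14.7 ± 33.2, and RNF17 averaged 27.3 ± 33.0 against 3.69 ± 17.8. PIWIL4, which carries piRNAs, went the other way, with 0 RPM in every gonad cell and 17.2 RPM on average in embryo cells. Within the germ-cell-like cluster, where 16 embryo cells stand against the 9 gonad cells, the list's median was 0.88, with 9 members higher and 3 lower. Taken from medians over cells instead of means, the list's difference over all cells was 0. Among 9 measured meiosis genes 1 was higher and 1 lower, and the median was 0.39. STRA8, which starts meiosis, and NANOS2, a gene of later male germ cells, had 0 reads in all 34 cells, which allows up to 0.198 RPM over the gonad cells.

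The germ cell specification list had a median of 0.67 over all cells, with 4 of 14 members higher and 3 lower, but this value turned with the cells compared. Within the germ-cell-like cluster the median was -0.63, with 3 members higher and 6 lower, and without the E20 embryo cells it was -0.41. The clusters were built from the same levels, so part of the turn within the cluster was built in. SOX17 and TFAP2C, which set up the primate germ cell programme, averaged 326 ± 154 and 201 ± 122 RPM in gonad cells, and 753 ± 423 and 548 ± 238 RPM in the 16 germ-cell-like embryo cells. T, the brachyury gene, averaged 104 ± 88.4 RPM against 482 ± 228 in those cells. NANOS3 and DPPA3, genes of established germ cells, were higher in gonad cells, at 69.4 ± 65.6 against 26.0 ± 25.3 RPM and 82.3 ± 66.9 against 32.9 ± 35.6 RPM. Pluripotency genes had a median of -0.34 over all cells, 0.022 without E36 cell 1 or cell 2, and -0.52 within the cluster, where POU5F1 averaged 1612 ± 555 against 4223 ± 1258 RPM and GDF3 19.8 ± 41.4 against 230 ± 273 RPM, while KLF4 was higher at 146 ± 80.7 against 83.6 ± 56.8 RPM. Primed epiblast genes had a median of -0.61 over all cells, -0.39 without E36 cell 4, -0.051 within the cluster and -2.12 within label code MS11.

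Genes of the DNA methylation machinery moved apart. DNMT3L, a cofactor of the enzymes that set new methylation, averaged 103 ± 61.5 RPM in gonad and 22.7 ± 31.0 in embryo cells. DNMT1, which maintains methylation at replication, averaged 34.8 ± 31.7 against 140 ± 95.7 RPM, and DNMT3B 21.3 ± 22.7 against 79.3 ± 82.1 RPM. Of the 10 members 1 was higher and 4 were lower, with a median of -0.57 over all cells and 0.03 within the germ-cell-like cluster. The histone and arginine methylation genes had a median of 0.13 and a mean of the opposite sign, -0.093. With single cells left out their median ran from 0.013 without E36 cell 1 to 0.26 without E36 cell 6, so it has no steady size.

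Over all cells, most mesoderm, WNT and BMP, and proliferation genes were at least 2-fold lower in gonad cells, and so were 9 of 19 amnion genes. The gastrulation and mesoderm list had a median of -1.57 (10 of 16 lower, 0 higher), the WNT and BMP response list -1.27 (14 of 20 lower, 1 higher), the amnion list -0.82 (9 of 19 lower, 2 higher, but 0.51 within label code MS11) and the migration and adhesion list -0.71 (6 of 14 lower, 2 higher). KRT19, an epithelial keratin, was 43.1-fold lower at 5.24 ± 7.97 against 226 ± 166 RPM and reached 15 RPM in 2 of 9 gonad and 24 of 25 embryo cells. Without E55 cell 1 it was 70.5-fold lower. FN1, the fibronectin gene, was 193-fold lower, at 5.22 ± 5.39 against 1007 ± 2462 RPM, with 11410 RPM in E16 cell 8, and 109.8-fold lower without that cell. Within the germ-cell-like cluster FN1 was 15.9-fold lower. This fold rested largely on the E14 cell, which had 819 RPM and 1891 of the 2859 FN1 reads of the 16 embryo cells there. The 9 mesoderm-like cells all came from embryos, and within the germ-cell-like cluster the medians were -0.90 for gastrulation and mesoderm, -0.29 for WNT and BMP, -0.55 for amnion and -0.29 for migration. As the clusters were built from the same levels, part of this shrinking was built in. Proliferation genes held closer, at -1.16 over all cells (11 of 20 lower, 0 higher) and -1.03 within the cluster. MKI67, a marker of cycling cells, averaged 37.7 ± 74.2 against 146 ± 118 RPM, and reached 15 RPM in 2 of 9 gonad and 20 of 25 embryo cells. MCM4, a replication helicase gene, averaged 129 ± 71.1 against 101 ± 75.1 RPM. Among gonad cells the proliferation list mean was highest in E36 cell 5 (6.97) and E55 cell 2 (7.30), which also held somatic transcripts. In the other gonad cells it ran from 3.75 to 5.37.

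Gonadal somatic genes had the highest median of the lists, 1.37 (12 of 18 higher, 3 lower), and this rested on a few gonad cells. Without the E47 cell the median was 0.78, and without E36 cell 5, the E47 cell and E55 cell 2 it was -0.25, where all genes together had -0.39. These cells were left out for their somatic transcripts, so a fall was built in. The E47 cell held 15700 RPM of INSL3, a hormone of testicular Leydig cells, with 3053 RPM of CYP17A1 and 804 RPM of STAR, genes of steroid synthesis, beside 146 RPM of DAZL and 60.8 RPM of DDX4. E36 cell 5 held WT1 at 141, LHX9 at 330 and NR2F2 at 222 RPM, genes of gonadal somatic cells, and had 0 RPM of DDX4. E55 cell 2 held WT1 at 57.2 RPM with DDX4 at 129 RPM. Without these 3 cells and within the germ-cell-like cluster, the late germ cell list still had a median of 0.65 and the proliferation list -1.54.

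The medians of the remaining lists lay between -0.45 and 0.25. The endoderm median was 0.16 (from -0.0049 without the E47 cell to 0.39 without E17 cell 2), that of trophoblast genes -0.39 (-0.24 without E20 cell 3, or without E36 cell 1 or 6) and that of blood and endothelium -0.34 (-0.73 without E36 cell 6, and also further from 0 without E17 cell 2, E20 cell 1 or 8, E36 cell 1 or 4, or E55 cell 1 or 2). Neural and surface ectoderm genes were at -0.37 (-0.86 without E55 cell 2, -0.20 without E20 cell 3) and cell stress genes at -0.32 (-0.70 without E55 cell 2, -0.15 without E20 cell 3). Oxidative phosphorylation genes were at -0.19 (-0.32 without the E47 cell, -0.089 without E36 cell 4), HOX genes at -0.45 (0.64 within label code MS11, 0.30 within the germ-cell-like cluster, and -1.53 as log2 ratio of mean RPM) and ribosomal protein genes at 0.25. Cell stress genes were at -1.40 within the germ-cell-like cluster without the 3 gonad cells rich in somatic transcripts.

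Among genes that averaged at least 50 RPM and reached 15 RPM in 80% of the cells of the higher group, which leaves out DAZL (difference 5.01) and DDX4 (4.82), the largest differences toward gonad cells were those of CRHBP, which binds corticotropin-releasing hormone (159.6 ± 84.9 against 35.95 ± 76.9 RPM, chromosome 6, difference 4.67), SPATA22, a meiotic recombination gene (83.9 ± 61.4 against 17.2 ± 34.3 RPM, chromosome 16, 4.14), and DRAM1, a p53 target (94.4 ± 79.1 against 14.3 ± 26.3 RPM, chromosome 11, 4.07). TCL1A and TCL1B, which bind the AKT kinase, differed by 3.90 and 3.92. The others were NLRP7 (3.99), NSMAF (3.59), the adhesion gene NCAM1 (3.56), CYTH1 (3.53), ACTG2 (3.45), the hormone gene GIP (3.43) and DPPA3 (3.36). Toward embryo cells, KRT19 (-5.79, chromosome 16) and FN1 (-4.47, chromosome 12) were joined by the metalloprotease gene ADAM19 (-4.53), BEX1 (-4.17), UBL4A (-3.81), PMEL (-3.78), FAM54A (-3.70), the ephrin gene EFNA1 (-3.60), RAB34 (-3.57), ASS1 (-3.49) and MKI67 (-3.47). Each of these genes kept its direction within the germ-cell-like cluster. Stage and organ cannot be told apart here. Within label code MS11, which the 2 E17 cells shared with the gonad cells, the late germ cell list stood at 0.81 and KRT19 at -6.11, and DAZL had 0 reads at E17, while FN1 (-0.31), NCAM1 (0.40) and the proliferation list (-0.26) differed less and the germ cell specification list was at -0.49.

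**Figure D2:**
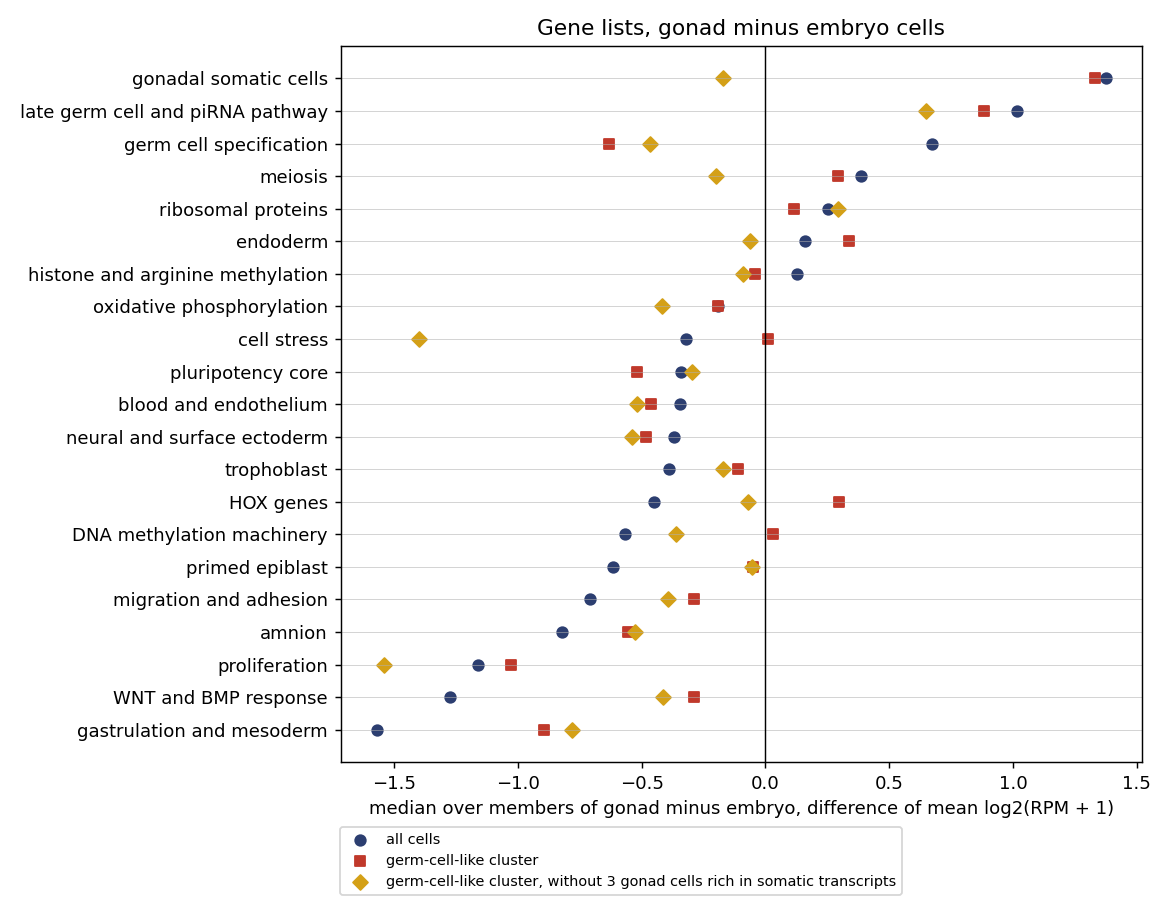
Median over list members of the gonad minus embryo difference in mean log2(RPM + 1) (horizontal) for 21 lists (vertical), for all cells (circles), the germ-cell-like cluster (squares) and that cluster without 3 gonad cells rich in somatic transcripts (diamonds). Late germ cell genes stood at 1.02, 0.88 and 0.65 (0 over all cells with medians over cells), whereas germ cell specification went from 0.67 to -0.63 and gonadal somatic cells from 1.37 to -0.17.

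E20 was compared with E16, the embryo stages with the most cells, to see how embryo cells differed across the days around gastrulation. Most E20 cells held little of the germ cell programme that E16 cells carried, and more of the transcripts of mesoderm and patterning. NANOG, a pluripotency gene kept by germ cells, averaged 154 ± 248 RPM in 8 E20 cells and 1173 ± 594 RPM in 11 E16 cells. SOX17 averaged 147 ± 202 against 743 ± 484 RPM, TFAP2C 135 ± 294 against 462 ± 238 RPM and SOX15 76.5 ± 122 against 277 ± 132 RPM. PRTG, a cell-surface receptor of the early embryo, averaged 489.7 ± 335.5 against 22.0 ± 59.8 RPM. It reached 15 RPM in 2 of 11 E16 cells, and the highest of them, at 200.9 RPM, carried most of the E16 mean. All 8 E20 cells reached 15 RPM of PRTG, the lowest at 30.98 RPM.

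The cells compared differed in cluster, and the clusters were built from the same levels. E20 cells 1 to 7 were mesoderm-like, and E20 cell 8 and 10 of 11 E16 cells were germ-cell-like. E20 cell 8 alone, which shared code MS09 with the E16 cells, had 566 RPM of NANOG, 537 RPM of SOX17 and 846 RPM of TFAP2C, and its germ cell specification median against E16 was 0.28, where all E20 cells gave -2.57. E20 cell 5 held both sets, with NANOG at 534, SOX17 at 236, TFAP2C at 191 and SOX15 at 271 RPM beside FN1 at 4265 RPM.

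Of 15 germ cell specification genes 13 were at least 2-fold lower at E20 and 0 higher, and of 15 pluripotency genes 10 were lower and 2 higher (median -2.08). POU5F1 averaged 809 ± 570 against 3852 ± 1449 RPM, and GDF3, a growth factor of pluripotent cells, 0.384 ± 0.412 against 168 ± 202 RPM, while LIN28B, which blocks the let-7 microRNAs, was higher at 166 ± 100.4 against 15.6 ± 33.3 RPM. Late germ cell and piRNA pathway genes had a median of -1.04 (9 of 18 lower, 1 higher), with PIWIL2 at 5.34 ± 7.55 against 56.2 ± 69.5 RPM. The list's median was -0.18 with medians over cells, -0.36 with a pseudocount of 10 and -1.90 as log2 ratio of mean RPM. Meiosis genes had a median of -0.36. Within the germ-cell-like cluster, 1 E20 cell against 10 E16 cells, the germ cell specification median was 0.09.

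Toward E20, HOX genes had a median of 1.54 (24 of 30 higher, 0 lower) and WNT and BMP response genes 2.34 (13 of 20 higher, 1 lower). ID3, a target of BMP signals, averaged 686 ± 552 against 64.7 ± 121 RPM, BMP4 144 ± 135 against 31.6 ± 99.8 RPM, and LEF1, a transcription factor of WNT signals, 141 ± 99.4 against 11.4 ± 36.8 RPM. At E16 only 1 cell reached 15 RPM of LEF1, at 122 RPM, and it carried most of that mean. Gastrulation and mesoderm genes had a median of 1.16 (8 of 16 higher, 1 lower), which was 2.11 without E16 cell 8 and lower by over 1.5 times without any 1 of E20 cells 1 to 5, lowest at 0.48 without cell 2. PDGFRA averaged 98.9 ± 77.0 against 19.3 ± 58.4 RPM, and HAND1 431 ± 494 against 166 ± 496 RPM, where E16 cell 8 held most of the HAND1 of its stage. T was 3.78-fold higher in mean RPM at E20, at 1313 ± 1745 against 347 ± 173 RPM, but lower in mean log2 (-0.36), because 3 E20 cells held most of it, and it was 2.52-fold higher without E20 cell 2. For E20 cell 8 alone against all 11 E16 cells, where all genes together had a median of -0.57, the HOX median was -0.088, the WNT and BMP median 0.058 and the mesoderm median -0.48. Against the 10 germ-cell-like E16 cells they were 0.96 (5 of 11 HOX genes higher, 0 lower), 0.52 and 0.095. In this 1 cell these lay at the 99.96, 95.5 and 98.4 percentiles of matched lists, whose medians were -0.86, -0.53 and -0.89.

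Amnion genes had a median of 1.05 (9 of 17 higher, 2 lower), with MSX1 at 312 ± 299 against 21.7 ± 61.9 RPM and IGFBP3 at 422 ± 499.7 against 8.74 ± 12.6 RPM, and -0.33 for E20 cell 8 alone. Genes of the DNA methylation machinery had a median of 1.64 (7 of 10 higher, 1 lower), and -0.70 for E20 cell 8 alone. UHRF1, which guides DNMT1 to replicated DNA, averaged 131 ± 97.8 against 16.1 ± 24.5 RPM, DNMT1 208 ± 106 against 90.6 ± 65.0 RPM, and DNMT3L 1.93 ± 4.79 against 30.5 ± 30.4 RPM. Primed epiblast genes had a median of 1.08 (7 of 14 higher, 2 lower), which was 0.58 without E20 cell 2 and -0.50 for E20 cell 8 alone. For gonadal somatic genes, which share collagens with mesoderm, it was 1.08 (0.69 without E20 cell 6), and COL1A1 averaged 1796 ± 2546 against 49.9 ± 42.1 RPM. For E20 cell 8 alone, all genes together had a median of -0.57. Within the germ-cell-like cluster this cell lay at the 94.5 percentile of matched lists for primed epiblast, 79.9 for amnion and 49.1 for DNA methylation genes.

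Smaller or less stable medians stood at 1.17 for trophoblast (0.75 without E20 cell 3, -0.42 for E20 cell 8 alone), 1.38 for the 4 measured neural and surface ectoderm genes (-0.31 for E20 cell 8 alone), 0.58 for proliferation, and 0.52 for migration and adhesion (0.29 without E16 cell 1, also lower without E20 cell 1, and 0.79 without E16 cell 8). Cell stress stood at 0.47 (0.20 without E20 cell 4, also lower without E20 cell 1, and 0.73 without E20 cell 5), histone and arginine methylation at -0.53 (-0.21 without E20 cell 7, and also nearer 0 without E16 cell 4 or E20 cell 2, 4 or 8), oxidative phosphorylation at -0.45 (-0.20 without E20 cell 2) and ribosomal proteins at -0.22 (-0.13 without E20 cell 6). Endoderm stood at -0.58 but at 0.16 without E16 cell 8, and blood and endothelium at 0.50 but at -0.27 without E20 cell 1 and -0.70 for E20 cell 8 alone. The values for E20 cell 8 alone stand beside a median of -0.57 over all genes. Within the germ-cell-like cluster this cell lay at the 90.4 percentile of matched lists for trophoblast, 91.9 for neural and 67.9 for blood genes.

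By the same rule, the genes with the largest differences toward E20 were PRTG (6.43, chromosome 7), the actin-binding gene PALLD (5.77), MSX1 (5.69), CDK6, a cell cycle kinase (5.64), HMGA2, a chromatin protein of embryonic cells (5.59), IGDCC3 (5.55), HAPLN1 (5.54), the retinoic acid-binding gene CRABP2 (5.49), the glucose transporter gene SLC2A1 (5.49), LEF1 (5.40) and the histone variant gene H2AFY (5.18). Toward E16 they were NANOG (-6.14, chromosome 11), GIP (-5.72), XIST, the RNA that silences an X chromosome (-5.70), GDF3 (-5.44), ELAVL2 (-5.41), GLRX (-5.31), NLRP2 (-5.04), CDO1 (-4.99), SOX15 (-4.97), TFCP2L1 (-4.87), CPEB1 (-4.86) and the cathepsin gene CTSL2 (-4.80). XIST averaged 139 ± 123 RPM at E16 and 0.583 ± 0.735 RPM at E20, and the gene paired with human EIF1AY, which the table places on chromosome 20, averaged 12.9 ± 27.4 and 57.7 ± 37.2 RPM. Among cells from male gonads, XIST stood at 53.0 RPM in E36 cell 5, which was rich in somatic transcripts, and at 0 in the other 5 E36 cells, at 10.9 RPM in the E47 cell, and at 30.7 and 9.42 RPM in the E55 cells. XIST reached 15 RPM in 10 of 11 E16 cells and in 0 of the other 14 embryo cells, and its antisense partner TSIX reached 25 RPM in E16 cell 2. Of the X and Y list's other genes, JPX, DDX3Y, KDM5D, UTY, USP9Y, ZFY, RPS4Y1 and SRY are not among the genes analysed here.

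**Figure D3:**
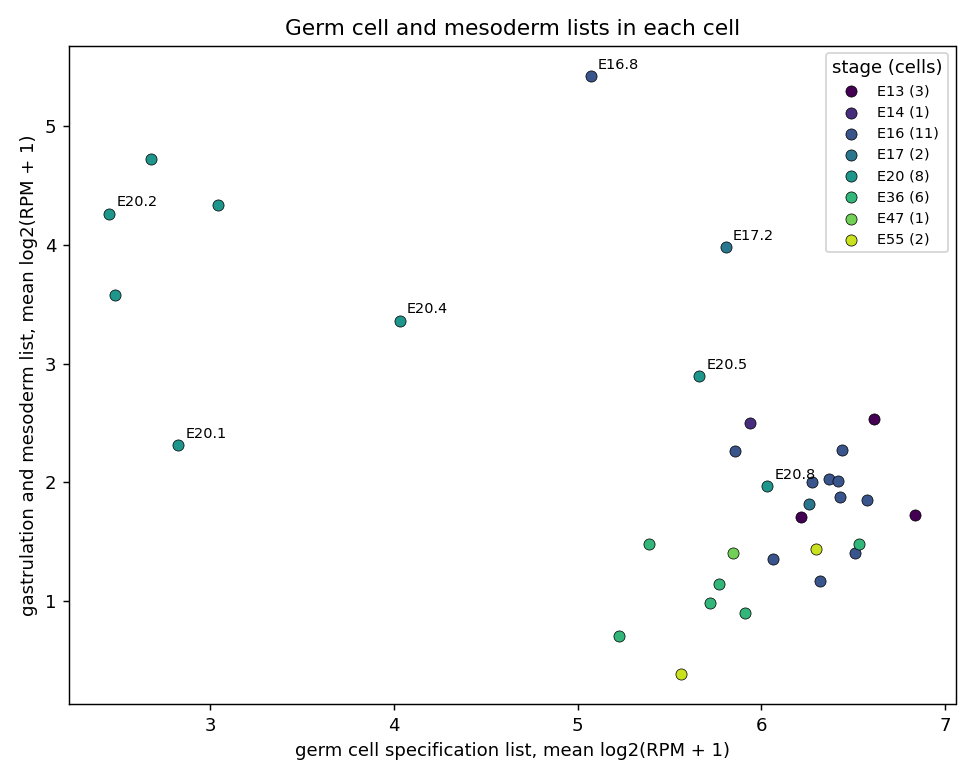
Mean log2(RPM + 1) of the germ cell specification list (horizontal) and of the gastrulation and mesoderm list (vertical), with 1 point per cell coloured by stage. T belongs to both lists. E20 cells ran from 2.45 to 6.03 on the germ cell axis, while E36 cells stayed between 5.23 and 6.53 with at most 1.48 on the mesoderm axis.

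The earliest cells already carried germ cell transcripts. At E13, SOX17 averaged 470 ± 300.5 RPM and TFAP2C 411 ± 174 RPM over 3 cells, with NANOG at 1182 to 1447 RPM in each cell and PECAM1, an adhesion gene shared with endothelium, at 401 to 724 RPM. The germ cell specification list averaged 6.56 ± 0.31 at E13, 6.21 ± 0.43 at E16 and 3.65 ± 1.45 at E20. The E14 cell combined 1241 RPM of SOX17 and 1052 RPM of TFAP2C with the highest SOX2 of the 34 cells, 37.7 RPM, and with 342 RPM of DNMT3B, both genes of the epiblast. Its primed epiblast list averaged 5.20, against 2.84 ± 0.11 at E13. The E17 cells differed from each other. Cell 1 held 829 RPM of SOX17 and 598 RPM of TFAP2C. Cell 2 held 863 RPM of CER1 and 372 RPM of LHX1, genes of the anterior endoderm and mesoderm, with 420 RPM of EOMES. Both carried germ cell transcripts: cell 1 had 10 and cell 2 had 11 of 14 germ cell markers at 15 RPM. Their germ cell specification means were 6.26 and 5.81.

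**Figure D4:**
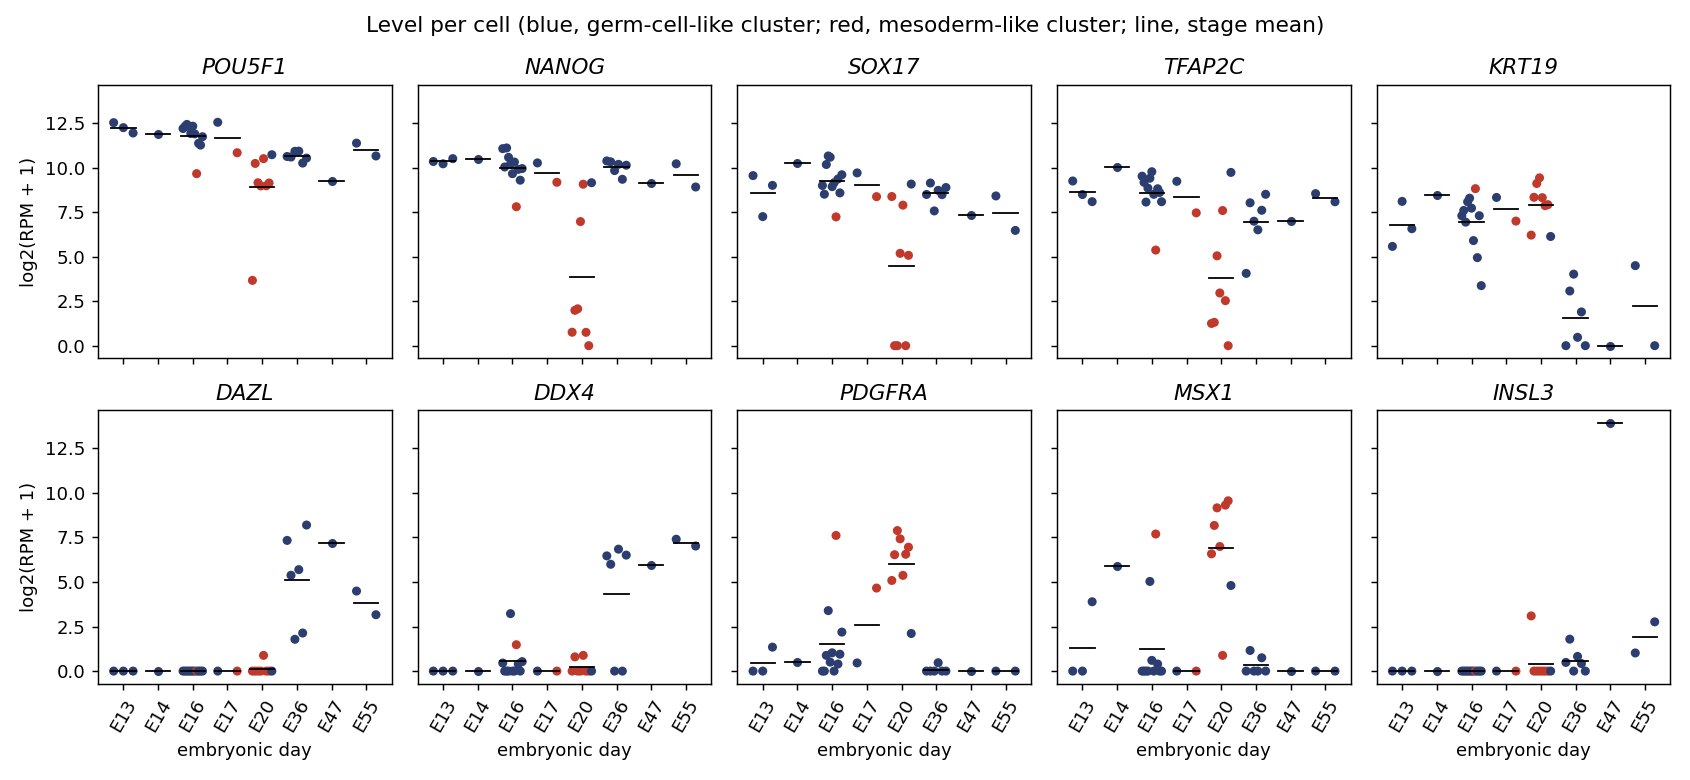
Log2(RPM + 1) (vertical) of 10 genes by stage (horizontal), 1 point per cell, blue for germ-cell-like and red for mesoderm-like cells, with a line at each stage mean. DAZL and DDX4 lay below 15 RPM in all 25 embryo cells, and INSL3 stood out in the E47 cell.

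E55 was compared with E36 to see how gonadal germ cells differed with time in the male gonad, with 2 cells against 6 and the E47 cell as a single value. KIT, a receptor of migrating and gonadal germ cells, averaged 569 ± 147 RPM at E55 and 202 ± 113 at E36, and DDX4 149 ± 27.7 against 59.1 ± 48.5 RPM. DAZL went the other way, at 14.7 ± 9.58 against 91.8 ± 114 RPM. TDRD12, a piRNA pathway gene, was at 0 in all E36 cells and averaged 20.54 ± 1.39 RPM at E55. All genes together had a median difference of 0.67, while the medians of matched random lists ran from -0.18 for ribosomal proteins to 1.09 for amnion genes, so each list is to be read against its own matched lists.

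The late germ cell list had a median of 1.65 (11 of 17 higher, 4 lower, at the 94.8 percentile of matched lists), with 1.0 without E55 cell 2, 2.63 without E55 cell 1, and 0.98 (7 of 15 higher, 4 lower, at the 81.0 percentile) without E36 cell 5 and E55 cell 2, the cells rich in somatic transcripts. In this list RNF17 averaged 65.8 ± 38.8 against 15.5 ± 25.9 RPM. Proliferation genes had a median of 1.36 (13 of 20 higher, 0 lower, at the 99.5 percentile), with 2.50 without E55 cell 1, and 1.04 (10 of 20 higher, 3 lower, at the 89.3 percentile) without those 2 cells. PLK1, a mitotic kinase, averaged 94.0 ± 8.36 against 33.3 ± 65.8 RPM. Primed epiblast genes had a median of -0.97 (at the 0.03 percentile of matched lists), which was -0.47 without E36 cell 5. Without those 2 cells it was -0.79, at the 11.2 percentile. Meiosis genes had a median of 1.56, which was -0.74 without E55 cell 2 and 3.15 without E55 cell 1. The pair of DNA methyltransferases that set new methylation moved apart, DNMT3A at 1.75 ± 0.43 against 51.3 ± 41.4 RPM and DNMT3B at 56.1 ± 0.42 against 8.35 ± 11.2 RPM, and the list's median was 0.13 (-0.49 without E55 cell 2, 0.68 without E36 cell 3).

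The other lists shifted when single cells were left out. Germ cell specification stood at 0.26 (0.58 without E55 cell 2), pluripotency at 0.40 (0.10 without E55 cell 1, 1.14 without cell 2) and gonadal somatic genes at 0.64 (-1.05 without E55 cell 2, which held WT1, and 1.79 without cell 1). With single cells left out, the endoderm median of 0.90 ran from -0.11 to 1.04, that of blood and endothelium (0.73) from -0.15 to 1.12, that of neural and surface ectoderm (0.99) from -0.76 to 2.02, and that of cell stress (0.77) from -0.67 to 0.94. The gastrulation and mesoderm median of -0.17 ran from -0.65 to 0.44, WNT and BMP response (0.11) from -0.13 to 0.52, and histone and arginine methylation (-0.21) from -0.25 to 0.45. Amnion genes (0.67) ran from 0.36 to 1.14, trophoblast genes (0.76) from 0.39 to 1.35, HOX genes (0.52) from 0.21 to 1.20, migration and adhesion genes (0.41) from 0.27 to 0.67, and oxidative phosphorylation genes (0.24) from 0.20 to 0.41. Ribosomal protein genes stood at -0.36. Amnion, trophoblast and HOX genes lay below the medians of their matched lists, 1.09, 0.79 and 0.56, at the 23.5, 48.2 and 48.4 percentiles. WNT and BMP response genes were at the 4.7, histone and arginine methylation genes at the 1.2 and ribosomal protein genes at the 4.4 percentile. The other lists of this paragraph lay from the 27.5 percentile (gonadal somatic) to the 82.3 (endoderm). Without E36 cell 5 and E55 cell 2, neural and surface ectoderm genes were at -0.91, cell stress genes at -0.67, gonadal somatic genes at -0.23 and HOX genes at 1.80.

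By the same rule, the genes with the largest differences toward E55 were TUBA3C, a testis tubulin gene (125 ± 35 against 0.821 ± 2.01 RPM, chromosome 10), SCG5 (279 ± 187 against 10.5 ± 15.9 RPM, chromosome 7), DKK3, SMARCAL1 and TUBA3E, with differences of 5.80, 5.77 and 5.76. SMTNL2 was at 0 in all 6 E36 cells and averaged 73.3 ± 2.2 RPM at E55. Toward E36 they were IFITM1, an interferon-induced membrane gene of primordial germ cells (468 ± 284 against 2.47 ± 0.60 RPM, chromosome 14, difference -6.66), TP53I3 (-5.85), PLCXD3 (-5.73), BACE2 (-4.90), AP3M1 (-4.62) and DYX1C1 (-4.61). With 2 cells at E55, 1 of them with somatic transcripts, these values describe the cells taken.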

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

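The tests for the E47 cell, for XIST and for the E20 cells were chosen after the values were seen. In each stage with 4 to 10 measured cells, E20 and E36, a cell was noted where it lay far from the nearest of the other cells of its stage. Of 199 groups of values examined, 41 held such a cell. The nominal 1 in 20, or about 10, holds for normal values and gives no chance level here. A gene found in only 1 cell of a stage is noted whatever its level, and many genes share the same cells. In 12 of the 41 no cell of the stage reached 15 RPM, so these rest on few reads.

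E20 cell 8, the germ-cell-like cell of its stage, had 2.711e+06 reads, above the 1072305 to 1564382 of the other 7 cells. It held less than the other E20 cells of several genes, with log2(RPM + 1) of 1.31 for CDK6, 3.07 for HMGA2, 1.51 for H2AFY, 1.84 for MKI67, 1.51 for UBL4A and 2.54 for TET1, and more of TUBA3E, at 4.88. E20 cell 1 had the highest blood and endothelium list mean, 4.15 against at most 1.41 in the others, with CDH5 at 1202 RPM, KDR at 598 RPM and PECAM1 at 317 RPM, and an oxidative phosphorylation mean of 7.75. Its POU5F1 was low at 3.66, and it held GLRX at 4.48, DNMT3L at 3.88, DYX1C1 at 3.41, DRAM1 at 2.98 and SPATA22 at 0.75. E20 cell 5, which carried germ cell and mesoderm transcripts together, stood apart in TUBA3C (3.77), TCL1A (2.38), DAZL (0.88) and LEF1 (0), and E20 cell 6 in UHRF1 (2.35).

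E36 cell 5, with transcripts of gonadal somatic cells, had 6789 genes at 15 RPM, above the 5233 to 5767 of the other E36 cells, and a HOX mean of 0.96. It alone held BEX1 (8.41), H2AFY (6.84), LEF1 (6.57), XIST (5.75) and SMARCAL1 (2.96) at its level, and its SPATA22 was low at 2.90. E36 cell 3 stood apart in PMEL (6.20), SLC2A1 (0.98), GDF3 (0.57) and CTSL2 (0.57), and E36 cell 4 in UBL4A (5.04), DKK3 (0.47) and PDGFRA (0.47). E36 cell 2 held TUBA3E (6.84) and TUBA3C (2.57), which the other 5 lacked, E36 cell 1 stood apart in TP53I3 (2.97) and the neural and surface ectoderm mean (0.96), and E36 cell 6 in DNMT3L (0).

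Most E20 cells held little of the germ cell programme. With all cells thinned to the same depth, the germ cell specification median was -2.56, which argues against depth. Thinned E20 cells had a median of 6732 genes at 15 RPM and E16 cells 6529, which argues against poorer libraries. No cell of another stage carries label code MS08, and 1 of its 7 cells had NANOG, SOX17, TFAP2C and SOX15 all at 15 RPM or more. Within E20, cell 8, coded MS09, had a germ cell specification mean of 6.03, and the MS08 cells ran from 2.45 to 5.66. The low levels thus went with the code inside this stage. As cell 8 is 1 cell and also differed in cluster, a batch of code MS08 cannot be told apart from the type of cell. The cells taken did differ in mix, with 7 of 8 E20 cells and 1 of 11 E16 cells mesoderm-like. The clusters were built from the same levels, so this mix describes the difference and does not test its cause. Whether the mix came from the stage or from the choice of cells stays open and was not tested.

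The E47 cell joined steroid-producing and germ cell transcripts. The labels name no cell type for it. Its germ cell specification mean lay 0.62 above that of the lowest other gonad cell, which argues against a purely steroid-producing cell. Its 10 most abundant genes took 5.33% of the reads, below the median of 7.54% in the other gonad cells, which argues against a few genes taking most of the reads. With 8016 genes at 15 RPM, above the 7555 of the next gonad cell, RNA of a second cell may be part of this library and stays open. No biological explanation was tested for this single cell.

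XIST was high in 10 of 11 E16 cells and near 0 in the other embryo cells. At the E16 level 2755 reads were expected in the 14 other embryo cells and 8 were seen, which argues against depth, and EIF1AX lay 0.27 higher in the 8 E16 cells with little of the gene paired with human EIF1AY, placed on chromosome 20, which argues against reads shared between these genes. The E20 cell with the code of the E16 cells had 0.369 RPM, and as it is 1 cell, a batch of that code cannot be told apart. X-linked genes had a median 0.69 higher in E16 cells than in the other germ-cell-like embryo cells, the highest of 21 chromosomes, where chromosome 17 followed at 0.52 and matched random lists had a median of 0.22, so a different sex of the embryo behind most E16 cells may play a part. It stays open, since stage, animal and code go together and 2 of 9 cells from male gonads also held XIST at 15 RPM or more, E36 cell 5, which was rich in somatic transcripts, and E55 cell 1.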

How the results depend on the processing

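The comparisons within the germ-cell-like cluster, those without gonad cells rich in somatic transcripts, and E20 against E16 with thinned cells were chosen after the data were seen. No paired analysis was possible because replicate numbers only name cells. Depth limits genes near the floor: over the gonad cells a count of 0 allows up to 0.198 RPM, and over E13 up to 1.58 RPM. Where a value below differs, the cause was not tested, except that settings with fewer cells or other members change the cells or genes by construction.

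Between gonad and embryo cells, 714 of 714 list medians stayed within 1 SD with single cells left out. This is a weak check, since leaving out 1 cell seldom shifts a list by 1 SD. Pluripotency still ran from -0.44 to 0.022 and gonadal somatic genes from 0.78 to 1.71. The 340 values of the 10 lists with a direction kept it, and 3 of 374 values of the lists under 0.5 changed sign. In 18 other settings 340 of 378 stayed within 1 SD, 28 moved and 10 turned, and 28 of 198 values of lists under 0.5 changed sign. The medians that turned were those of germ cell specification (-0.43 with medians over cells, -0.29 as log2 ratio of mean RPM, -0.49 within code MS11, -0.41 without E20, -0.63 within the germ-cell-like cluster and -0.47 there without 3 gonad cells rich in somatic transcripts), amnion (0.51 within MS11), DNA methylation (0.031 within the cluster) and gonadal somatic genes (-0.25 without the 3 cells, -0.17 with both changes). The 3 cells were left out for their somatic transcripts, so the fall of gonadal somatic genes was built in. The cluster was built from the same levels, so turns within it may also be partly built in. With a minimum of 15 RPM, meiosis moved to -1.36, trophoblast to -1.64 and HOX to -1.64. With medians over cells, late germ cell and gonadal somatic genes moved to 0. As log2 ratio of mean RPM, amnion moved to -2.42, gastrulation to -3.54, endoderm to -1.47, blood to -1.80 and HOX to -1.53. For E36 against E20, germ cell specification moved to 2.26, pluripotency to 1.49, amnion to -2.58, trophoblast to -1.56, gonadal somatic to 0.23, neural to -1.70, WNT and BMP to -3.41, migration to -1.24, HOX to -1.74 and ribosomal to 0.55. Within MS11, primed epiblast moved to -2.12, histone methylation to 0.66, trophoblast to 0.67, migration to -0.18 and HOX to 0.64. Migration moved to -0.16 with stage means and to -0.18 without E20, and stress to -1.40 within the cluster without the 3 cells. Of 384 values of named genes in other settings 17 moved and 0 turned, and of 816 with single cells left out 0 moved. That last count was fixed in advance, since leaving out 1 cell of groups this large cannot shift a gene's mean by 1 SD. Counts of members 2-fold higher or lower moved in 104 of 1428 values with single cells left out and in 195 of 756 in other settings.

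Between E20 and E16, 397 of 399 list medians stayed within 1 SD with single cells left out and 2 turned. Endoderm ran from -0.80 to 0.16 and blood from -0.27 to 0.72. In 10 other settings 168 of 210 stayed, 29 moved and 13 turned, and 3 of 40 values of lists under 0.5 changed sign. With E20 cell 8 alone, all genes together had a median of -0.57 within code MS09 and -0.53 within the germ-cell-like cluster. A changed sign there need not be a change against other genes. All 13 that turned rest on E20 cell 8 alone. Within code MS09 they were germ cell specification 0.28, primed epiblast -0.50, DNA methylation -0.70, amnion -0.33, gastrulation -0.48, trophoblast -0.42, blood -0.70, neural -0.31 and HOX -0.088, and within the germ-cell-like cluster germ cell specification 0.089, DNA methylation -0.43, amnion -0.084 and blood -0.62. Others moved there, within MS09 to -0.68 for pluripotency, 0.058 for WNT and BMP, 0.012 for oxidative phosphorylation and 0.45 for ribosomal genes, and within the cluster to -0.55 for pluripotency, 0.044 for primed epiblast, 0.13 for trophoblast, 0.21 for neural, 0.52 for WNT and BMP, -0.030 for oxidative phosphorylation and 0.35 for ribosomal genes. A pseudocount of 0.1 moved pluripotency to -2.80, late germ cell to -1.88 and HOX to 2.55, and one of 10 moved them to -1.27, -0.36 and 0.68, and neural to 0.56. With no minimum level, trophoblast moved to 0.12, gonadal somatic to 0.072 and neural to 0. With a minimum of 15 RPM, gonadal somatic moved to 2.48 and HOX to 2.42. Late germ cell moved to -0.18 with medians over cells. As log2 ratio of mean RPM, germ cell specification moved to -1.47, late germ cell to -1.90, endoderm to -2.0, gonadal somatic to 1.98 and HOX to 2.80. Of 192 values of named genes 42 moved and 10 turned, again with E20 cell 8 alone. Within MS09 these were CDK6 -0.030, HAPLN1 -0.10, CRABP2 -0.70, H2AFY -0.42, SOX15 0.16, TFCP2L1 0.59 and CPEB1 0.87, and within the cluster CRABP2 -0.029, TFCP2L1 0.25 and CPEB1 0.56. Of 456 values of named genes with single cells left out 0 moved, which the size of the groups again fixed in advance. Counts of members moved in 62 of 798 values with single cells left out and in 124 of 420 in other settings.

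Between E55 and E36, 155 of 168 list medians stayed within 1 SD with single cells left out, 6 moved and 7 turned, and 11 of 72 values of lists under 0.5 changed sign. The ranges were 0.10 to 1.14 for pluripotency, 1.0 to 2.63 for late germ cell, -0.74 to 3.15 for meiosis, -0.25 to 0.45 for histone methylation, -0.11 to 1.04 for endoderm, -1.05 to 1.79 for gonadal somatic, -0.15 to 1.12 for blood, -0.76 to 2.02 for neural, -0.67 to 0.94 for stress and 0.20 to 0.41 for oxidative phosphorylation. In 8 other settings 139 of 168 stayed, 25 moved and 4 turned, and 12 of 72 values of lists under 0.5 changed sign. Neural turned to -0.48 as log2 ratio of mean RPM, where late germ cell moved to 0.70, gastrulation to -1.12 and migration to 0.067. Without the 2 cells rich in somatic transcripts, gonadal somatic turned to -0.23, neural to -0.91 and stress to -0.67, and pluripotency moved to 1.04 and HOX to 1.80. A pseudocount of 0.1 moved meiosis to 3.02, endoderm to 1.90, neural to 2.10 and HOX to 1.45, and one of 10 moved late germ cell to 0.54 and meiosis to 0.42. With no minimum level, late germ cell moved to 0.19, endoderm to 0.30, and meiosis, amnion and neural to 0. With a minimum of 15 RPM, DNA methylation moved to 0.93, histone methylation to 0.47, blood to 1.94, neural to 3.22, WNT and BMP to -0.90 and HOX to 1.44. Medians over cells moved endoderm to 1.64 and oxidative phosphorylation to 0.064, and size factors moved ribosomal genes to -0.47. Of 72 values of named genes 25 moved and 0 turned, and of 96 with single cells left out 10 moved. Counts of members moved in 60 of 336 values with single cells left out and in 95 of 336 in other settings.

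Median genes per cell at E16, E20 and E36 moved to 9852, 9620 and 8513 at 1 RPM and to 3858, 3876 and 3504 at 50 RPM, and stayed within 1 SD when thinned. The number of clusters stayed at 2. Of 120 gene levels at embryo stages 5 moved with medians over cells, and of 390 values with single cells left out 12 moved.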

Other observations

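The E20 cells differed in the transcripts they held. E20 cells 2, 6 and 7 held T at 4381, 1656 and 3593 RPM with WNT3A, a signal of the primitive streak, at 214, 541 and 199 RPM. E20 cells 3 and 4 held COL1A1 at 7363 and 2940 RPM with HAND1 at 728 and 1533 RPM and ISL1 at 177 and 120 RPM. E16 cell 8 held TTR at 3099 RPM and APOA1 at 1430 RPM, genes of visceral and yolk sac endoderm, with HAND1 at 1660 RPM. It also had the most genes at 15 RPM of all cells, 8106, with 11 germ cell and 8 mesoderm markers at that level. RNA of a second cell was not tested for this library. These cells were singled out after their values were seen.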
